A study of Synechocystis sp. PCC 6803 with 26 samples.

How the data were processed

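RNA from the wild type, from a mutant labelled ccmM and from a double mutant labelled ∆glcD1/∆glcD2, written glcD1D2 in the group names, at high carbon or after a shift to low carbon, was hybridised to custom Agilent oligonucleotide arrays with 2 colours. Per the labels, each of the 26 samples is 1 channel, Cy5 or Cy3, and per the file headers each file holds both channels of its array, so that the 26 files were 13 arrays deposited in 2 identical copies each. They lay on 4 slides: the WT_LC24h arrays on slide 1, the ccmM arrays on slide 2, the glcD1D2_LC24h arrays on slide 3, and the WT_LC3h, glcD1D2_LC3h and glcD1D2_HC against WT_HC arrays on slide 4. Samples were put into 8 groups by their labels, which gave 7 kinds of array. The labels do not say whether replicates are separate cultures, so every p-value measures only the spread between these samples. The labels give no time at low carbon for ccmM.

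The deposited intensity values are the median pixel brightness of each spot and of its local background on a linear scale, made with Agilent Feature Extraction 9.5.1.1 per the file headers, with no further normalization. The deposited processed intensities were background-subtracted and dye-normalized by that software, per the file headers. The authors' value table holds log2 values whose making is not stated. Each of its columns correlated at 0.992 or above with the log2 signal of its own channel, and its within-array differences correlated at 0.929 to 0.998 with the ratios computed here, which settled its scale and its direction relative to the files. The column medians lay between 8.78 and 12.98, and how the columns were centred stays unknown.

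Each array has 15208 spots, of which 536 are controls. The design fixed before the files were seen assumed mean signals, and median signals were used for all arrays because 2 arrays lack mean signals. Background was corrected with normexp (offset 50), ratios were normalized within each array by loess with controls and outlier spots at weight 0, spots were averaged per probe and probes per gene, on the log2 scale. The 8091 probes gave 3264 genes, of which 61 had 1 probe, 1611 had 2, 1560 had 3 and 32 had 4. Genes with a channel well above background on at least 2 arrays were to be tested, which removed 0 genes, and 2771 genes were well above background in both channels on all arrays. For levels per sample, channels were additionally put on a common scale between arrays (Aquantile).

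All 13 arrays entered 1 limma fit with a coefficient for each kind of array, so that both samples of an array were compared within it and the comparisons shared an estimate of the spread (6 residual and 3.04 prior degrees of freedom). Tests were limma's moderated tests, two-sided, adjusted by Benjamini-Hochberg over 3264 genes, and a gene passed at an adjusted p under 0.05. The dye could not be a covariate, because each group of a comparison carried 1 dye. A gene's dye bias cancels in the mean responses, in their difference between 24 h and 3 h and in the differences between the mutants, and enters doubled in the glcD1D2 response minus the WT response. The mean of a group on 2 arrays rests on few values, and the number of arrays limits the precision of all ratios. ccmM_LC had 1 array and was described by ratios of at least 2-fold and by the percentile of each list's median among 10000 random lists of the same size, matched on mean level.

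The 19 lists, with 231 genes, were written by hand before the files were seen: induced and constitutive uptake of inorganic carbon, the flavodiiron operon with the antiporter cluster, carbon regulators, carboxysome and Rubisco, photorespiration, nitrogen, phycobilisome, photosystem I, photosystem II, high light and heat stress, iron, phosphate, ATP synthase, NDH-1 core, ribosomal proteins, Calvin cycle, sugar catabolism and glycogen, and tetrapyrroles. They were tested with camera in limma at its preset correlation between genes (0.01), adjusted over all lists and comparisons, and again with the correlation estimated per list, which is the value given after "or". Of 247 list tests 122 passed with the preset and 0 with the estimated correlation. The targeted gene was left out of a list in its own mutant's comparison. "Over the list alone" means adjusted by Benjamini-Hochberg within the list's genes. The text names, by a rule fixed before the data were examined, the targeted genes, 10 low carbon markers, the genes with the largest changes per comparison (adjusted p under 0.05, at least 2-fold, same direction on its arrays) and the members of each list with the highest and lowest ratios. Some genes that this rule would name are not reported here, many of them because their call or size rested on 1 array. The gene table supplied matched 0 of the array's locus tags, so symbols come from the hand-written lists, other genes are named by locus tag and only a few are named.

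The fit was tested on simulated data with known changes. Of 50 genes changed 2-fold it recovered 40 for WT_LC24h, 28 and 24 between the strains at 24 h and 3 h and 24 to 48 over all comparisons, and of 50 changed 4-fold 44 to 50. Unchanged genes were 3.03% of the calls for WT_LC24h and over 5% for glcD1D2_LC24h (5.08%) and 24 h against 3 h (7.14%). Of 13 shifted lists 13 passed and of 13 unshifted 0. Correlated genes and unequal array spread were not tested there. Alternatives set before the data were examined were no background correction, the scanner's processed signals, the authors' value table, no filter on dim probes, leaving out each array in turn, a dye-bias correction and a fit by group without the shared array. The dye-bias correction subtracted each gene's median Cy5 over Cy3 ratio over the 7 kinds of array, which sets the kind with the middle ratio to 0 by construction (214 to 782 genes per kind), so that a value moved to 0 by it does not show a dye bias. The fit by group used single-channel levels and took no account of which samples shared an array. It joined channels of different arrays by their labels, so its values rest on those labels being right. A stricter filter and fits without the glcD1D2_LC3h arrays, of slide 4 alone and with the replicate number as a block in place of the array were chosen after seeing the data. The pairing of samples comes from the shared array. Deviations of the 2 channels from their group means correlated across genes at -0.119 on the ccmM_HC arrays and at 0.337 to 0.824 on the other replicated kinds. Both samples carry 1 replicate number on 13 of 13 arrays, so the comparison within arrays also blocks on it. Antisense and overlapping transcripts were not examined. Computations used R 4.3.3, limma 3.58.1, jsonlite 2.0.0 and the data.table package (version 1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 for the plots.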

Results

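Transcript levels of Synechocystis, a unicellular cyanobacterium, were measured on 2-colour oligonucleotide arrays. The samples came from the wild type (WT), from a mutant labelled ccmM and from a double mutant labelled ∆glcD1/∆glcD2, written glcD1D2 in the group names here. The ccmM product holds the carboxysome, the compartment that concentrates CO2 around Rubisco, together, and glcD1 and glcD2 encode glycolate dehydrogenases of the photorespiratory pathway. Cells were labelled as high carbon (HC, 5% CO2) or low carbon (LC, 0.035% CO2), with 3 h or 24 h at LC given for WT and glcD1D2 and no time given for ccmM. The 26 samples were the 2 dye channels of 13 arrays: 8 samples were labelled WT_HC, 2 WT_LC24h, 2 WT_LC3h, 3 ccmM_HC, 1 ccmM_LC, 6 glcD1D2_HC, 2 glcD1D2_LC24h and 2 glcD1D2_LC3h. Each pair of conditions set against each other on an array had 2 arrays, except ccmM_LC against ccmM_HC with 1 array. The number of arrays limits the precision of every value. In each channel at least 70.5% of the spots were well above background, and the median spot signal lay between 387 and 9338 in Cy5 and between 474 and 6881 in Cy3. Expression of 3264 genes was tested.

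The targeted genes were read first in every sample, as a check of the labels. On the 2 arrays that set ccmM_HC against WT_HC, ccmM stood at a log2 level of 13.90 ± 0.14 (SD, n = 2) in the samples labelled ccmM_HC and at 10.54 ± 0.10 in those labelled WT_HC, so that it was 10.3-fold higher (log2 3.36, SE 0.34, adjusted p = 0.000845) in the samples carrying the mutant's label. Its 3 probes gave log2 ratios of 2.96 to 3.71 on these arrays. This direction goes against the label of a ccmM mutant. On the array that set ccmM_LC against ccmM_HC, the ccmM level was 9.48 in the sample labelled ccmM_HC and 9.53 in that labelled ccmM_LC, both below every other sample. The remaining samples labelled WT_HC had ccmM levels of 12.84 ± 0.20, 13.28 ± 0.13 and 11.57 ± 0.38 (SD, n = 2 each) on the WT_LC24h, WT_LC3h and glcD1D2_HC arrays. WT_LC24h stood at 13.41 ± 0.16 and WT_LC3h at 12.99 ± 0.22, while glcD1D2_HC stood at 13.67 ± 0.58, 12.48 ± 0.59 and 12.01 ± 0.79 on its 3 kinds of array, glcD1D2_LC24h at 11.59 ± 0.84 and glcD1D2_LC3h at 11.49 ± 0.18. Because of this, samples are named by their labels, and every direction rests on these and may be reversed. Exchanging the dyes on all arrays gave the lowest spread within groups and would turn each ratio within arrays. Fits that ignore the shared array would not simply turn.

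For glcD1, single samples ranged from a log2 level of 10.10 to 11.39 over all 26 samples, and for glcD2 from 9.63 to 12.43. Between glcD1D2_HC and WT_HC neither passed the test, with glcD1 (log2 0.30, SE 0.17, adjusted p = 0.20) and glcD2 (log2 0.42, SE 0.24, adjusted p = 0.195). The part deleted in the double mutant is not given in the sources used here, and probes that lie outside it check nothing, so these values neither bear out nor contradict the labels of the double mutant.

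The first question was how the wild type differed after 24 h at low carbon. Genes for the induced uptake of inorganic carbon were lower in the samples labelled WT_LC24h than in those labelled WT_HC, which is opposite to their textbook induction at low carbon. cmpA, which encodes the substrate-binding protein of the BCT1 bicarbonate transporter, was 24.4-fold lower (log2 -4.61, SE 0.32, adjusted p = 3.61e-05) on 2 arrays. sbtA, which encodes a sodium-dependent bicarbonate transporter, was 27.6-fold lower (log2 -4.79, SE 0.41, adjusted p = 0.000107). cupA, ndhF3 and ndhD3, subunits of an inducible CO2-uptake form of NADPH dehydrogenase, fell with log2 ratios of -3.96, -3.49 and -3.45. All 10 genes listed as induced uptake systems fell, 10 also when adjusted over the list alone. The induced uptake median was -3.47 (adjusted p = 1.08e-13, or 0.126 with estimated correlation), -1.21 in the fit by group without the shared array (the group fit) and -4.17 with processed signals. Of the constitutive uptake list, 2 rose (the same over the list alone). The constitutive uptake median was 0.37 (adjusted p = 0.0440, or 0.552 with estimated correlation).

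flv2, flv4 and sll0218, an operon for flavodiiron proteins of photosystem II and a small membrane protein, were among the genes with the largest falls. flv2 was 36.5-fold lower (log2 -5.19, SE 0.37, adjusted p = 3.61e-05), and sll0218 (log2 -4.67) and flv4 (log2 -4.59) fell with it. In the list that joins this operon to the slr2006 to slr2013 antiporter genes, 7 fell (9 fell over the list alone). The flavodiiron and antiporter median was -0.62 (adjusted p = 6.12e-06, or 0.305 with estimated correlation), -1.37 with processed signals. Of the 5 carbon regulators, 2 fell, among them ndhR (log2 -1.54), a repressor of uptake genes (3 fell over the list alone), and the list had a median of -0.73 (adjusted p = 0.0291, or 0.492 with estimated correlation). Without array 1 ndhR did not pass (log2 -1.05).

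psbA3 and psbA2, which encode the D1 protein of photosystem II, were 14.7-fold lower (log2 -3.88, SE 0.20, adjusted p = 1.02e-05) and 13-fold lower (log2 -3.70, SE 0.24, adjusted p = 2.60e-05). Among 15 photosystem II genes 2 rose and 8 fell (the same over the list alone). The photosystem II median was -0.89 (adjusted p = 0.00191, or 0.552 with estimated correlation). The photosystem I core genes psaA (log2 -2.33) and psaB (log2 -2.30) fell, and of 12 listed photosystem I genes 4 fell (5 fell over the list alone). That list had a median of -0.97 (adjusted p = 0.00044, or 0.552 with estimated correlation), 0.01 in the group fit and -2.13 with the dye-bias correction. Of 12 NDH-1 core genes 9 fell (the same over the list alone), with ndhI (log2 -2.54) and ndhK (log2 -1.94). The NDH-1 core median was -1.48 (adjusted p = 2.76e-08, or 0.121 with estimated correlation). Of 13 genes of the phycobilisome, the light-harvesting antenna, 2 fell (the same over the list alone), and the list had adjusted p = 0.385.

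Ribosomal protein genes were higher in the samples labelled WT_LC24h: 22 of 23 rose (13 without array 1), 23 over the list alone, led by rpl14 (log2 2.65, SE 0.27) and rpl5 (log2 2.62, SE 0.23). The ribosomal protein median was 2.02 (adjusted p = 2.15e-18, or 0.298 with estimated correlation), 0.78 in the group fit. ATP synthase genes followed the same sign, with 6 of 9 rising (0 and 1 without array 1 or 2), 9 over the list alone. The ATP synthase median was 1.69 (adjusted p = 0.000144, or 0.552 with estimated correlation), 0.85 with the dye-bias correction. In the high light and heat stress list 3 rose and 3 fell (4 rose and 3 fell over the list alone), with the chaperonin gene groEL1 (log2 3.18) higher. Its median (-0.32) and mean (0.24) differed in sign and the test pointed up (adjusted p = 0.848). Nitrogen genes went both ways, as of 20 genes 10 rose and 4 fell (10 rose and 5 fell over the list alone). The gene gifA (log2 -4.86), for an inhibitor of glutamine synthetase, fell (adjusted p = 0.0512 for the list). No carboxysome or Rubisco gene of 12 passed, also over the list alone (adjusted p = 0.562), and of 12 photorespiration genes 3 rose and 2 fell (3 rose and 3 fell over the list alone), and the list had adjusted p = 0.674. Outside the lists, the gene with the locus tag slr0373 (log2 -5.77) fell. groEL1 did not pass (log2 3.19) without array 1.

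Over all genes, limma called 654 of 3264 between WT_LC24h and WT_HC, 292 higher and 362 lower in the samples labelled WT_LC24h, and 289 of them differed at least 2-fold. The count was 101 without array 1, 1101 without background correction, 1459 with the scanner's processed signals and 1100 with the authors' value table. In the group fit limma called 0 genes, with 231 at an unadjusted p under 0.05. Of 17 lists with a call, 15 and 5 moved by over 1.5 times in count without array 1 or 2, 9 and 2 of them to 0.

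The second question was the wild-type difference after 3 h at low carbon. cmpA was 42.3-fold lower (log2 -5.40, SE 0.32, adjusted p = 3.20e-05) in the samples labelled WT_LC3h than in those labelled WT_HC on 2 arrays, and sbtA was 26.4-fold lower (log2 -4.72, SE 0.41, adjusted p = 0.000171), again opposite to textbook induction. hliB, which encodes a high-light-inducible chlorophyll-binding protein, was 28.5-fold lower (log2 -4.83, SE 0.55, adjusted p = 0.000708). slr2006, the first gene of the antiporter cluster, was 11.4-fold lower (log2 -3.51, SE 0.14, adjusted p = 4.09e-06). All 10 induced uptake genes fell, also over the list alone, including cmpB (log2 -4.09) and sbtB (log2 -3.49). For the induced uptake list the median was -3.37 (adjusted p = 2.15e-18, or 0.121 with estimated correlation), -0.97 in the group fit. All 11 genes of the flavodiiron and antiporter list fell, 11 over the list alone, with flv2 (log2 -3.96), sll0218 (log2 -3.58) and flv4 (log2 -3.51). For the flavodiiron and antiporter list the median was -1.97 (adjusted p = 2.91e-14, or 0.121 with estimated correlation), -0.27 in the group fit. The activator gene cmpR and the repressor gene ndhR were the 2 of 5 carbon regulators that fell (2 over the list alone), with log2 ratios of -2.42 and -2.35. The carbon regulator median was -0.54 (adjusted p = 0.00412, or 0.305 with estimated correlation).

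NDH-1 core genes were lower as well, with 10 of 12 falling (10 over the list alone), among them ndhI (log2 -2.28). For the NDH-1 core list the median was -1.66 (adjusted p = 1.05e-10, or 0.121 with estimated correlation), -0.97 in the group fit. Of 12 photosystem I genes 2 fell (3 fell over the list alone). The photosystem I median was -0.32 (adjusted p = 0.0348, or 0.664 with estimated correlation), 0.62 in the group fit and -1.44 with the dye-bias correction. Of 15 photosystem II genes 3 fell (4 fell over the list alone), with psbA3 (log2 -1.92). For the photosystem II list the median was -0.46 (adjusted p = 0.00192, or 0.552 with estimated correlation), 0.40 in the group fit. Among 12 carboxysome and Rubisco genes 3 fell (the same over the list alone), and the list had adjusted p = 0.0800. Of 4 constitutive uptake genes 1 rose and 1 fell (the same over the list alone), with bicA (log2 -1.32) lower (adjusted p = 0.309 for the list). Genes of nitrogen metabolism went both ways, as of 20 genes 6 rose and 4 fell (8 rose and 4 fell over the list alone), and the list had adjusted p = 0.0700.

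Of 23 ribosomal protein genes 3 rose (the same over the list alone). For the ribosomal protein list the median was 0.28 (adjusted p = 0.00337, or 0.624 with estimated correlation). None of 9 ATP synthase or 13 phycobilisome genes passed (0 over the list alone, adjusted p = 0.932 and 0.775). In the high light and heat stress list 1 rose and 6 fell (4 rose and 7 fell over the list alone), hliB among them. Its median (0.05) and mean (-0.35) differed in sign and the test pointed down (adjusted p = 0.195). Of 12 photorespiration genes 2 fell (the same over the list alone), with sll1559 (log2 -1.23), and the list had adjusted p = 0.165. By locus tag alone, ssr2016 (log2 -3.71) fell and ssr1251 (log2 3.36) rose. limma called 373 genes, 170 higher and 203 lower in the samples labelled WT_LC3h, 193 of them at least 2-fold. The count was 53 without array 1 and 100 without array 2, and limma called 0 genes (390 at an unadjusted p under 0.05) in the group fit. Of 17 lists with a call, 15 and 12 moved by over 1.5 times in count without array 1 or 2, 9 and 6 of them to 0.

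In the glcD1D2 mutant, 24 h at low carbon was set against high carbon on 2 arrays. The uptake gene cmpA was 24.5-fold lower (log2 -4.62, SE 0.32, adjusted p = 4.02e-05) in the samples labelled glcD1D2_LC24h, and sbtA was 18.8-fold lower (log2 -4.23, SE 0.41, adjusted p = 0.000221). psaA and psaC, which encode the reaction centre protein and an iron-sulfur subunit of photosystem I, were 25.4-fold lower (log2 -4.67, SE 0.29, adjusted p = 2.4e-05) and 20.5-fold lower (log2 -4.36, SE 0.33, adjusted p = 5.45e-05). cpcA and cpcB, the phycocyanin subunits, were 17.4- and 17.2-fold lower (log2 -4.12, SE 0.42, and log2 -4.11, SE 0.50). In the opposite direction, hliB was 9.78-fold higher (log2 3.29, SE 0.55, adjusted p = 0.00369). All 10 induced uptake genes fell, 10 over the list alone, including cmpB (log2 -4.23), ndhD3 (log2 -4.00), cupA (log2 -3.59) and ndhF3 (log2 -2.62). The induced uptake median was -3.52 (adjusted p = 1.92e-14, or 0.121 with estimated correlation), -0.92 in the group fit. The flavodiiron operon fell with flv2 (log2 -4.30), sll0218 (log2 -3.65) and flv4 (log2 -3.01), whereas the other 8 genes of its list did not pass (3 fell over the list alone). The flavodiiron and antiporter median was -0.28 (adjusted p = 0.00201, or 0.497 with estimated correlation). Without array 1 hliB did not pass (log2 3.10).

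In the photosystem I list 11 of 12 genes fell, 11 over the list alone. For the photosystem I list the median was -3.08 (adjusted p = 2.43e-11, or 0.353 with estimated correlation), -2.19 in the group fit and -2.06 with the dye-bias correction. Of 13 phycobilisome genes 10 fell (11 fell over the list alone), 5 without array 1, with cpcC1 (log2 -4.37). The phycobilisome median was -2.54 (adjusted p = 1.31e-07, or 0.497 with estimated correlation), -1.90 in the group fit and -1.68 with the dye-bias correction. Of 15 photosystem II genes 8 fell (10 fell over the list alone), with psbB (log2 -2.17). The photosystem II median was -1.05 (adjusted p = 5.97e-05, or 0.497 with estimated correlation), -0.37 with the dye-bias correction. Of 12 NDH-1 core genes 10 fell (1 rose and 10 fell over the list alone), with ndhI (log2 -2.13) and ndhJ (log2 -2.08). The NDH-1 core median was -1.24 (adjusted p = 4.48e-07, or 0.126 with estimated correlation). Carboxysome and Rubisco genes included rbcX (log2 -3.43), and of 12 genes 1 rose and 4 fell (2 rose and 7 fell over the list alone). The carboxysome and Rubisco median was -0.96 (adjusted p = 0.0454, or 0.624 with estimated correlation). Of 17 high light and heat stress genes 8 rose (10 rose over the list alone). The light and heat stress median was 1.14 (adjusted p = 0.000197, or 0.552 with estimated correlation), 0.40 with the dye-bias correction. Ribosomal protein genes rose in 17 of 23 cases (3 and 1 without array 1 or 2), 22 over the list alone. The ribosomal protein median was 0.95 (adjusted p = 3.18e-10, or 0.492 with estimated correlation). None of 9 ATP synthase genes and of 10 photorespiration genes, here without glcD1 and glcD2, passed (0 over the list alone, adjusted p = 0.104 and 0.836). Of 20 nitrogen genes 1 rose and 2 fell (2 fell over the list alone), with gltB (log2 -1.49) lower, and the test pointed down (adjusted p = 0.915) while median (0.05) and mean (0.03) lay above 0. Of 5 carbon regulators 1 fell (3 fell over the list alone), and the list had adjusted p = 0.109. By locus tag, sll0330 (log2 3.63) rose.

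limma called 622 genes between glcD1D2_LC24h and glcD1D2_HC, 291 higher and 331 lower in the samples labelled glcD1D2_LC24h, 287 of them at least 2-fold. Without array 1 the count was 214, with the dye-bias correction 323, without background correction 935, with processed signals 1173 and 1079 with the authors' value table. The group fit called 1 gene and turned flv4 to a log2 ratio of 0.39. Of 16 lists with a call, 12 and 7 moved by over 1.5 times in count without array 1 or 2, 4 and 1 of them to 0.

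In the glcD1D2 mutant after 3 h at low carbon, psaA was 3.48-fold lower (log2 -1.80, SE 0.29, adjusted p = 0.0329) in the samples labelled glcD1D2_LC3h on 2 arrays, psbF, a subunit of cytochrome b559 in photosystem II, was 2.83-fold lower (log2 -1.5, SE 0.26, adjusted p = 0.0329), and the antenna linker gene cpcG1 was 2.57-fold lower (log2 -1.36, SE 0.25, adjusted p = 0.0356). The uptake genes cmpA and sbtA did not pass: cmpA (log2 0.93, SE 0.32, adjusted p = 0.155) and sbtA (log2 0.63, SE 0.41, adjusted p = 0.438). The 2 arrays disagreed on them, with 1.79 on array 1 and 0.06 on array 2 for cmpA, and 1.79 and -0.53 for sbtA. None of the 10 induced uptake genes passed (0 higher and 1 lower over the list alone). Their median (-0.10) and mean (0.03) differed in sign, with the test pointing down (adjusted p = 0.834). No flavodiiron, antiporter, carbon regulator, carboxysome or Rubisco gene passed (0 over the list alone), with flv2 (log2 0.21, SE 0.37, adjusted p = 0.798). The flavodiiron and antiporter list had a median of 0.12 with the test pointing down (adjusted p = 0.991). Of 12 photosystem I genes 2 fell (9 fell over the list alone). The photosystem I median was -0.95 (adjusted p = 1.85e-07, or 0.497 with estimated correlation), -2.12 in the group fit and 0.00 with the dye-bias correction. Of 13 phycobilisome genes 2 fell (5 fell over the list alone), with a median of -1.07 (adjusted p = 1.20e-05, or 0.552 with estimated correlation), -1.97 in the group fit and 0.00 with the dye-bias correction. Among 15 photosystem II genes 1 fell (7 fell over the list alone). For the photosystem II list the median was -0.42 (adjusted p = 0.000113, or 0.497 with estimated correlation), 0.00 with the dye-bias correction. The dye-bias correction sets 782 genes to 0 here by construction, which is no evidence for or against a dye bias. Among 12 NDH-1 core genes 1 fell (4 fell over the list alone). For the NDH-1 core list the median was -0.41 (adjusted p = 0.000268, or 0.298 with estimated correlation). No gene of the high light and heat stress list passed (1 rose over the list alone). For the light and heat stress list the median was 0.52 (adjusted p = 0.00795, or 0.629 with estimated correlation), -0.24 with the dye-bias correction. No ATP synthase, ribosomal protein, nitrogen or constitutive uptake gene passed (0 over the list alone), and of 10 photorespiration genes 1 fell (the same over the list alone), and the list had adjusted p = 0.495. limma called 82 genes, 35 higher and 47 lower in the samples labelled glcD1D2_LC3h, 28 of them at least 2-fold. The 2 arrays correlated at r = 0.508 across genes, which are not independent replicates. limma called 0 genes (292 at an unadjusted p under 0.05) without array 1, 6 without array 2 and 0 (311) in the group fit, against 254 with slide 4 alone, 133 with the authors' value table and 24 (6 higher and 18 lower) with the dye-bias correction. With either array left out 0 genes were left in the 5 lists with a call. psaA, psbF and cpcG1 did not pass (log2 -1.65, -1.69 and -1.56) without array 1. Without array 2 psaA, psbF and cpcG1 did not pass (log2 -1.95, -1.32 and -1.16), and cmpA and sbtA passed (log2 1.79 and 1.79).

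**Figure D1:**
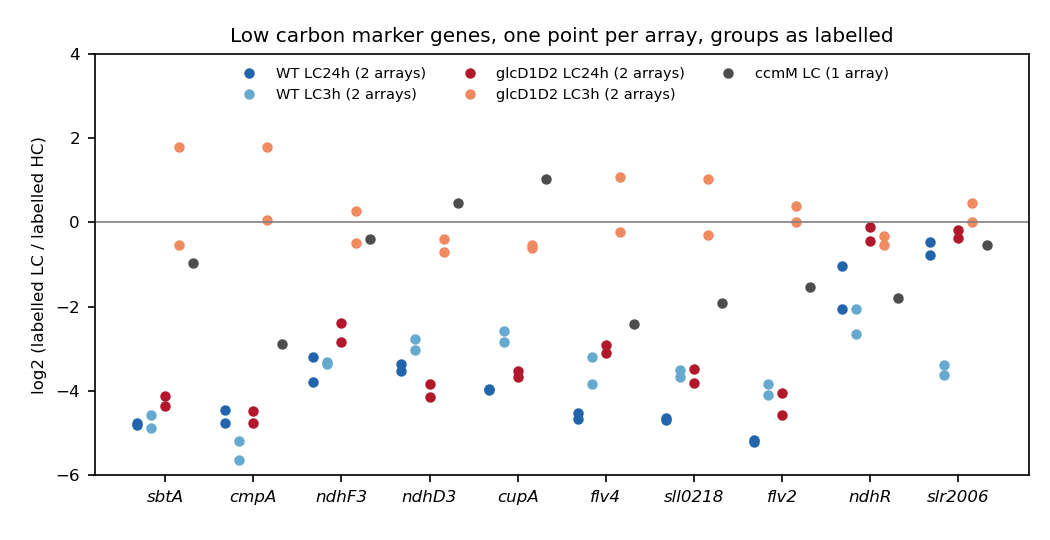
Log2 ratio (LC over HC, as labelled) of the 10 low carbon markers in each LC comparison, with a point for each array. The mean of cmpA lay at -4.61, -5.40 and -4.62 in WT_LC24h, WT_LC3h and glcD1D2_LC24h and at 0.93 in glcD1D2_LC3h.

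Averaging the WT and glcD1D2 ratios at one time cancels a gene's dye bias, because HC was in Cy5 on the WT arrays and in Cy3 on the glcD1D2 arrays. In this mean 24 h response (4 arrays) flv2 was 26.8-fold lower (log2 -4.74, SE 0.26, adjusted p = 4.62e-06), cmpA was 24.5-fold lower (log2 -4.61, SE 0.23, adjusted p = 3.03e-06) and sbtA was 22.8-fold lower (log2 -4.51, SE 0.29, adjusted p = 1.17e-05) in the LC samples as labelled. All 10 induced uptake genes fell, also over the list alone. For the induced uptake list the median was -3.39 (adjusted p = 1.92e-14, or 0.121 with estimated correlation), -1.03 in the group fit and -3.98 with processed signals. Of 11 flavodiiron and antiporter genes 8 fell (9 fell over the list alone), with sll0218 (log2 -4.16) and flv4 (log2 -3.80). For the flavodiiron and antiporter list the median was -0.45 (adjusted p = 1.27e-05, or 0.337 with estimated correlation). Among 12 photosystem I genes 10 fell (the same over the list alone), with psaA (log2 -3.50). For the photosystem I list the median was -2.19 (adjusted p = 4.71e-09, or 0.445 with estimated correlation), -1.15 in the group fit. Among 13 phycobilisome genes 10 fell (the same over the list alone), with cpcA (log2 -2.21). For the phycobilisome list the median was -1.23 (adjusted p = 4.07e-05, or 0.552 with estimated correlation). Of 12 NDH-1 core genes 10 fell (the same over the list alone), with ndhI (log2 -2.33). The NDH-1 core median was -1.40 (adjusted p = 2.60e-08, or 0.121 with estimated correlation), -0.81 in the group fit. Ribosomal protein genes rose in 22 of 23 cases, 23 over the list alone, with rpl14 (log2 1.90). For the ribosomal protein list the median was 1.48 (adjusted p = 3.03e-17, or 0.298 with estimated correlation), 0.61 in the group fit. The chaperonin genes groES (log2 2.48) and groEL2 (log2 2.23) rose. limma called 822 genes in the mean 24 h response, 352 higher and 470 lower.

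In the mean 3 h response (4 arrays), cmpA was 4.72-fold lower (log2 -2.24, SE 0.23, adjusted p = 0.000738) and sbtA was 4.14-fold lower (log2 -2.05, SE 0.29, adjusted p = 0.00288) in the LC samples as labelled. Again all 10 induced uptake genes fell, 10 over the list alone. The induced uptake median was -1.72 (adjusted p = 1.92e-14, or 0.121 with estimated correlation), -1.07 in the group fit. Flavodiiron and antiporter genes fell in 9 of 11 cases, 10 over the list alone, including flv2 (log2 -1.88) and slr2006 (log2 -1.64). The flavodiiron and antiporter median was -1.12 (adjusted p = 1.85e-10, or 0.143 with estimated correlation), -0.41 in the group fit. limma called 365 genes, 154 higher and 211 lower. The 24 h count was 1258 without background correction, 1526 with processed signals, 1314 with the authors' value table, 356 without WT_LC24h array 1 and 468 without glcD1D2_LC24h array 1, and the 3 h count was 601 with slide 4 alone and 81 to 195 with any one of its arrays left out. In the group fit limma called 0 genes at either time, with 152 and 82 at an unadjusted p under 0.05. At 24 h: of 17 lists with a call, 2 to 10 moved by over 1.5 times in count with an array left out, 1 to 2 of them to 0. At 3 h these were 7 to 12 and 4 to 8.

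The difference between the mean 24 h and the mean 3 h response tested the time at low carbon, although 3 h arrays lay on slide 4 and 24 h arrays on slides 1 and 3. In this mean over strains uptake genes were lower at 24 h than at 3 h, with cupA (log2 -2.14, SE 0.21), ndhD3 (log2 -2.00, SE 0.15), cmpA (log2 -2.38, SE 0.32) and sbtA (log2 -2.46, SE 0.41), and of 10 induced uptake genes 8 fell (10 fell over the list alone). For the induced uptake list the median was -1.91 (adjusted p = 6.37e-11, or 0.175 with estimated correlation), -0.01 in the group fit. By strain, cmpA stood in WT at -4.61 at 24 h and -5.40 at 3 h and the induced uptake median at -3.47 and -3.37, and in glcD1D2 these were -4.62 and 0.93, and -3.52 and -0.10. hliB was 7.54-fold higher (log2 2.91, SE 0.55, adjusted p = 0.0138) and slr2006 was 2.28-fold higher (log2 1.19, SE 0.14, adjusted p = 0.00193). flv2 was 7.29-fold lower (log2 -2.87, SE 0.37, adjusted p = 0.00287), so that of 11 flavodiiron and antiporter genes 2 rose and 3 fell (the same over the list alone), with a median of 0.15, a mean of -0.37 and a test pointing up (adjusted p = 0.482). Of 23 ribosomal protein genes, 21 were higher (4 to 20 with an array left out), 22 over the list alone, with rpl5 (log2 1.69). The ribosomal protein median was 1.32 (adjusted p = 1.35e-16, or 0.305 with estimated correlation), 0.11 in the group fit. Of 12 photosystem I genes 7 fell (10 fell over the list alone), with psaA (log2 -1.68). The photosystem I median was -1.37 (adjusted p = 3.36e-06, or 0.499 with estimated correlation), -0.35 in the group fit. limma called 324 genes, 137 higher and 187 lower at 24 h. The count was 523 without background correction, 741 with processed signals, 597 with the authors' value table and between 97 and 122 without WT_LC24h array 1, either WT_LC3h array or glcD1D2_LC3h array 1, and 191 without glcD1D2_LC24h array 1. limma called 0 genes (199 at an unadjusted p under 0.05) in the group fit, which turned cmpA and flv2 to 0.25 and 0.05. Of 14 lists with a call, 4 to 8 moved by over 1.5 times in count with an array left out, 0 to 4 of them to 0. hliB did not pass (log2 2.85) without WT_LC24h array 1. Without WT_LC3h array 1 hliB did not pass (log2 2.82). hliB did not pass (log2 3.01) without WT_LC3h array 2.

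Whether the strains responded differently was tested as the glcD1D2 response minus the WT response, where a dye bias enters doubled. At 24 h the glutamine synthetase inhibitor gene gifA was 49.7-fold higher (log2 5.63, SE 0.60, adjusted p = 0.00223) and psbA3 was 14.0-fold higher (log2 3.81, SE 0.28, adjusted p = 0.000897) in the glcD1D2 response, with psbA2 (log2 3.54) of the same sign. cpcB was 15.8-fold lower (log2 -3.98, SE 0.70, adjusted p = 0.0153) and cpcA was 14.1-fold lower (log2 -3.82, SE 0.60, adjusted p = 0.010). Of 13 phycobilisome genes 6 fell (9 fell over the list alone). The phycobilisome median was -2.13 (adjusted p = 9.95e-06, or 0.552 with estimated correlation), 0.01 with the dye-bias correction. Of 12 photosystem I genes 6 fell (10 fell over the list alone). For the photosystem I list the median was -1.70 (adjusted p = 1.26e-06, or 0.497 with estimated correlation), 0.44 with the dye-bias correction. Of 23 ribosomal protein genes 8 fell (16 fell over the list alone). For the ribosomal protein list the median was -1.03 (adjusted p = 1.17e-06, or 0.540 with estimated correlation), -0.40 in the group fit. Of the 10 induced uptake genes, 1 was lower and 9 did not pass (0 higher and 2 lower over the list alone), with cmpA (log2 -0.01, SE 0.45, adjusted p = 0.994) and sbtA (log2 0.55, SE 0.59, adjusted p = 0.544), and the list had adjusted p = 0.674. limma called 312 genes, 164 higher and 148 lower in the glcD1D2 response. The count was 72 with the dye-bias correction, 12 and 106 without WT array 1 or 2, 78 without glcD1D2 array 1, and 763, 1129 and 811 without background correction, with processed signals and with the authors' value table. In the group fit limma called 0 genes (422 at an unadjusted p under 0.05). Of 14 lists with a call, 9 to 14 moved by over 1.5 times in count with an array left out, 4 to 12 of them to 0. Without WT_LC24h array 1 cpcB and cpcA did not pass (log2 -3.88 and -3.73). cpcB did not pass (log2 -4.08) without WT_LC24h array 2. Without glcD1D2_LC24h array 1 cpcB and cpcA did not pass (log2 -3.80 and -3.65).

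At 3 h the strains differed in the uptake genes: cmpA was 80.4-fold higher (log2 6.33, SE 0.45, adjusted p = 0.000235), sbtA was 40.8-fold higher (log2 5.35, SE 0.59, adjusted p = 0.00126) and hliB was 98.2-fold higher (log2 6.62, SE 0.78, adjusted p = 0.00182) in the glcD1D2 response than in the WT response. All 10 induced uptake genes were higher, 10 over the list alone, including ndhF3 (log2 3.22) and cmpB (log2 4.86). The induced uptake median was 3.01 (adjusted p = 2.15e-18, or 0.121 with estimated correlation), 0.03 in the group fit. Of 11 flavodiiron and antiporter genes 8 rose (11 rose over the list alone), with flv2 (log2 4.17) and slr2006 (log2 3.74). For the flavodiiron and antiporter list the median was 1.70 (adjusted p = 2.68e-13, or 0.121 with estimated correlation), 0.47 in the group fit. Of 5 carbon regulators 2 rose (the same over the list alone), with cmpR (log2 2.67). For the carbon regulator list the median was 0.75 (adjusted p = 0.0188, or 0.445 with estimated correlation). Of 12 NDH-1 core genes 8 rose and 1 fell (9 rose and 1 fell over the list alone). For the NDH-1 core list the median was 1.24 (adjusted p = 2.69e-06, or 0.154 with estimated correlation), 0.15 in the group fit and 0.61 with the dye-bias correction. limma called 193 genes, 98 higher and 95 lower. The count was 100 (66 higher and 34 lower) with the dye-bias correction, 52 in the group fit, 313 with slide 4 alone and 33 to 81 with any one of its arrays left out. Of 10 lists with a call, 6 to 9 moved by over 1.5 times in count with an array left out, 2 to 5 of them to 0. cmpA, sbtA and cmpB stood at log2 5.46, 4.19 and 4.16 without glcD1D2_LC3h array 1. Without glcD1D2_LC3h array 2 cmpA, sbtA and cmpB stood at log2 7.20, 6.51 and 5.56.

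At high carbon, the mutants were set against the wild type. In the samples labelled ccmM_HC, flv2 was 37.3-fold lower (log2 -5.22, SE 0.37, adjusted p = 0.000145), sll0218 was 27.6-fold lower (log2 -4.79, SE 0.39, adjusted p = 0.000216) and flv4 was 24.9-fold lower (log2 -4.64, SE 0.41, adjusted p = 0.000386) than in those labelled WT_HC on 2 arrays. The phycocyanin genes cpcB and cpcA were 13.7-fold higher (log2 3.77, SE 0.50, adjusted p = 0.00259) and 12.2-fold higher (log2 3.61, SE 0.42, adjusted p = 0.00149). Since ccmM itself was higher here, these directions rest on labels that it goes against. SEs and p-values use a spread shared by all arrays and may be too small here. These 2 arrays differed most (single-array SD 0.527, against 0.0893 to 0.338). Next to ccmM, its operon neighbour ccmN, another carboxysome gene, was 6.83-fold higher (log2 2.77, SE 0.33, adjusted p = 0.00160). Of the other 11 carboxysome and Rubisco genes 1 rose and 2 fell (the same over the list alone), with a median of -0.14, a mean of 0.20 and a test pointing up (adjusted p = 0.940). Of 13 phycobilisome genes 11 rose (12 rose over the list alone), 2 without array 2. For the phycobilisome list the median was 2.25 (adjusted p = 9.95e-08, or 0.497 with estimated correlation), 0.44 in the group fit and 1.5 with the dye-bias correction. All 9 ATP synthase genes rose (0 without array 2), 9 over the list alone. For the ATP synthase list the median was 2.18 (adjusted p = 2.01e-05, or 0.540 with estimated correlation), 0.35 in the group fit and 1.49 with the dye-bias correction. Among 12 photosystem I genes 9 rose (11 rose over the list alone), 2 without array 2. Photosystem I had a median of 1.57 (adjusted p = 1.31e-06, or 0.497 with estimated correlation), -0.11 in the group fit and 0.63 with the dye-bias correction. The nitrate transporter gene nrtA (log2 3.55) rose, while nblA1 (log2 -3.72) and gifB (log2 -3.40) fell, and of 20 nitrogen genes 10 rose and 4 fell (12 rose and 4 fell over the list alone). The nitrogen median was 1.19 (adjusted p = 0.0169, or 0.552 with estimated correlation), 0.31 in the group fit and 0.37 with the dye-bias correction. flv2, sll0218, flv4, cpcB, cpcA, nblA1 and gifB stood at log2 -6.24, -5.69, -5.59, 5.21, 4.80, -5.44 and -4.35 without array 1. Without array 2 gifB did not pass (log2 -2.44), and flv2, sll0218, flv4, cpcB, cpcA and nblA1 stood at -4.20, -3.89, -3.69, 2.34, 2.42 and -2.00.

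Of 10 induced uptake genes, between the samples labelled ccmM_HC and WT_HC, 3 fell (the same over the list alone), with cupA (log2 -1.07) and ndhD3 (log2 -0.91) lower and cmpA (log2 -0.10, SE 0.32, adjusted p = 0.821), and the list had adjusted p = 0.0596, and of 4 constitutive genes 2 rose (3 rose over the list alone), and the list had adjusted p = 0.0524. Besides flv2, flv4 and sll0218 no flavodiiron or antiporter gene of 11 passed (3 fell over the list alone). The flavodiiron and antiporter median was -0.24 (adjusted p = 0.0450, or 0.568 with estimated correlation). Among 12 NDH-1 core genes 9 fell (10 fell over the list alone), with ndhI (log2 -1.41). The NDH-1 core median was -1.02 (adjusted p = 9.41e-06, or 0.175 with estimated correlation). Of 15 photosystem II genes 5 rose and 2 fell (6 rose and 2 fell over the list alone), and the list had adjusted p = 0.139. Of 17 high light and heat stress genes 3 rose and 6 fell (4 rose and 6 fell over the list alone), with hspA (log2 -3.03) lower (adjusted p = 0.221 for the list). No ribosomal protein gene of 23 passed (0 over the list alone), yet the list had a median of 0.41 (adjusted p = 0.00829, or 0.642 with estimated correlation), -0.14 in the group fit. Of 12 photorespiration genes 5 rose and 1 fell (5 rose and 3 fell over the list alone), and the list had adjusted p = 0.421. By locus tag, sll1862 (log2 -3.61) and slr0006 (log2 -3.21) fell. limma called 794 genes, 378 higher and 416 lower in the samples labelled ccmM_HC, 313 of them at least 2-fold. The 2 arrays correlated at r = 0.688 across genes. The count was 1330 without array 1, 72 without array 2, 220 with the dye-bias correction and 0 by limma (240 at an unadjusted p under 0.05) in the group fit. Among 17 lists with a call, 3 and 12 moved by over 1.5 times in count without array 1 or 2, 0 and 6 of them to 0. hspA stood at log2 -4.28 without array 1. Without array 2 hspA did not pass (log2 -1.79).

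In the samples labelled glcD1D2_HC, cpcB was 9.55-fold higher (log2 3.25, SE 0.50, adjusted p = 0.00190) than in those labelled WT_HC on 2 arrays. psbO, a subunit of the oxygen-evolving complex, was 7.40-fold higher (log2 2.89, SE 0.45, adjusted p = 0.00201) and psaA was 6.53-fold higher (log2 2.71, SE 0.29, adjusted p = 0.000562). rbcL, the large subunit of Rubisco, was 5.23-fold higher (log2 2.39, SE 0.45, adjusted p = 0.00419), and amt1, an ammonium transporter, was 9.43-fold higher (log2 3.24, SE 0.54, adjusted p = 0.00248). gifB was 17.6-fold lower (log2 -4.14, SE 0.49, adjusted p = 0.000716), nblA1 was 12.4-fold lower (log2 -3.63, SE 0.63, adjusted p = 0.00289) and hspA, a small heat shock protein gene, was 14.9-fold lower (log2 -3.90, SE 0.63, adjusted p = 0.00229). ccmM was also higher, by 4.30-fold (log2 2.10, SE 0.34, adjusted p = 0.00234). Among 13 phycobilisome genes 12 rose (the same over the list alone), 4 without array 1. The phycobilisome median was 2.36 (adjusted p = 1.04e-06, or 0.525 with estimated correlation), 1.15 in the group fit and 1.41 with the dye-bias correction. Of 12 photosystem I genes 11 rose (the same over the list alone), 5 without array 1. The photosystem I median was 1.95 (adjusted p = 1.17e-06, or 0.497 with estimated correlation), 1.05 in the group fit and 1.0 with the dye-bias correction. Of 15 photosystem II genes 10 rose (11 rose over the list alone), with psbF (log2 2.35). The photosystem II median was 0.80 (adjusted p = 3.31e-05, or 0.497 with estimated correlation). All 9 ATP synthase genes rose (0 without array 1), 9 over the list alone. The ATP synthase median was 2.07 (adjusted p = 0.000449, or 0.552 with estimated correlation), 0.71 in the group fit and 1.37 with the dye-bias correction. Of 12 carboxysome and Rubisco genes 8 rose and 1 fell (9 rose and 1 fell over the list alone). For the carboxysome and Rubisco list the median was 1.64 (adjusted p = 0.00556, or 0.552 with estimated correlation), 0.32 in the group fit. Among 17 high light and heat stress genes 8 fell (the same over the list alone). The light and heat stress median was -1.0 (adjusted p = 0.00283, or 0.624 with estimated correlation), -0.18 in the group fit and -0.23 with the dye-bias correction. Without array 1 cpcB, psbO, rbcL, amt1, nblA1, hspA and ccmM did not pass (log2 3.07, 2.44, 2.09, 2.03, -3.39, -3.18 and 1.43), and gifB stood at -3.48. Without array 2 amt1, gifB, hspA and ccmM stood at log2 4.44, -4.79, -4.61 and 2.78.

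Of 10 induced uptake genes 2 rose (0 passed over the list alone), with cmpA (log2 -0.12, SE 0.32, adjusted p = 0.787), and the list had adjusted p = 0.30. Among 5 carbon regulators 1 rose (the same over the list alone), the 1 being cyAbrB1 (log2 1.96), and the list had adjusted p = 0.520. Of 12 NDH-1 core genes 4 rose (5 rose and 1 fell over the list alone), with ndhD1 (log2 1.27). For the NDH-1 core list the median was 0.43 (adjusted p = 0.0233, or 0.497 with estimated correlation), -0.40 in the group fit. Of 20 nitrogen genes 8 rose and 3 fell (10 rose and 4 fell over the list alone), and the list had adjusted p = 0.0717. Of 10 photorespiration genes 1 rose and 3 fell (the same over the list alone). Their median (0.03) and mean (-0.12) differed in sign with the test pointing down (adjusted p = 0.880). limma called 1276 genes, 623 higher and 653 lower in the samples labelled glcD1D2_HC, 483 of them at least 2-fold. The count was 143 without array 1, 543 with the dye-bias correction and 149 in the group fit, which turned hspA to 0.26. Of 18 lists with a call, 17 and 5 moved by over 1.5 times in count without array 1 or 2, 8 and 2 of them to 0.

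The 2 mutant effects at high carbon were compared directly as ccmM_HC minus glcD1D2_HC, each against WT_HC, in which a dye bias cancels. flv2 was 31.5-fold lower (log2 -4.98, SE 0.52, adjusted p = 0.00209) and flv4 was 28.1-fold lower (log2 -4.81, SE 0.58, adjusted p = 0.00349) in the ccmM effect, as was the iron transporter gene futC (log2 -1.85). Of 12 NDH-1 core genes 9 fell (12 fell over the list alone), 1 without glcD1D2_HC array 1. The NDH-1 core median was -1.34 (adjusted p = 2.70e-10, or 0.121 with estimated correlation), -0.32 in the group fit. Of 11 carboxysome and Rubisco genes 3 fell (5 fell over the list alone). The carboxysome and Rubisco median was -1.30 (adjusted p = 0.0259, or 0.596 with estimated correlation), -0.33 in the group fit. Among 11 flavodiiron and antiporter genes 5 fell (6 fell over the list alone). For the flavodiiron and antiporter list the median was -0.65 (adjusted p = 6.65e-05, or 0.408 with estimated correlation), 0.30 in the group fit. limma called 246 genes, 100 higher and 146 lower in the ccmM effect. The count was 38 without glcD1D2_HC array 1 and 419 with the authors' value table. The group fit called 320, 210 higher and 110 lower, and turned flv2 and flv4 to 0.61 and 1.46. Of 12 lists with a call, 3 to 12 moved by over 1.5 times in count with an array left out, 0 to 8 of them to 0. flv2 and flv4 stood at log2 -5.99 and -5.76 without ccmM_HC array 1. Without ccmM_HC array 2 flv2 and flv4 stood at log2 -3.96 and -3.87.

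For ccmM, low carbon was set against high carbon on 1 array, without a stated time at low carbon, so these ratios have no replicate check and no test. gifB and nblA1 were 25.8- and 14.4-fold lower in the sample labelled ccmM_LC (log2 -4.69 and -3.85), cmpA was 7.35-fold lower (log2 -2.88) and sbtA had a log2 ratio of -0.96. rpl5, atpC and the glutamine synthetase gene glnA were 13.9-, 11.7- and 8.86-fold higher (log2 3.80, 3.55 and 3.15), and ccmM had a log2 ratio of 0.05. List medians were placed among 10000 random lists of the same size and similar mean level, as a description of this array. Of 10 induced uptake genes 1 stood higher and 4 stood lower by at least 2-fold, with a list median of -0.77 at percentile 0.390, with cmpB (log2 -2.01) and cupA (log2 1.02). Among 23 ribosomal protein genes 22 stood higher by at least 2-fold, with a list median of 2.59 at percentile 100. Of 9 ATP synthase genes 9 stood higher by at least 2-fold, with a list median of 2.81 at percentile 99.98, with atpH (log2 3.06). Among 20 nitrogen genes 9 stood higher and 4 stood lower by at least 2-fold, with a list median of 0.61 at percentile 99.5. Of 17 high light and heat stress genes 2 stood higher and 10 stood lower by at least 2-fold, with a list median of -1.37 at percentile 0, with sodB (log2 -2.54). Of 11 flavodiiron and antiporter genes 3 stood lower by at least 2-fold, with a list median of -0.50 at percentile 5.22, with flv4 (log2 -2.41). Over all genes, 595 differed at least 2-fold, 288 higher and 307 lower, and 104 in the group fit (81 higher and 23 lower), which turned gifB, nblA1 and flv4 to 0.24, 0.12 and 1.88.

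The ccmM response on this array was also set against the mean of the 2 glcD1D2 responses. rbcX, a Rubisco chaperone, was higher in the ccmM response by 4.72 on the log2 scale and psaD by 4.55, and gifB and hliB differed by -5.77 and -5.01, cpcB by 3.58, cupA by 3.10 and cmpA by -1.03. List medians differed by 3.58 for ATP synthase, 2.06 for ribosomal proteins, 2.22 for photosystem I, 2.58 for the phycobilisome and -1.83 for high light and heat stress. The first 4 were 1.47, 0.77, 1.49 and 1.49 in the group fit. The spread of the ccmM_LC array was not measured, and the 2 ccmM_HC arrays of its slide differed most. With the spread of the other arrays put in its place, limma gave 838 genes, a count that rests on this assumption and is not read as a difference found.

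**Figure D2:**
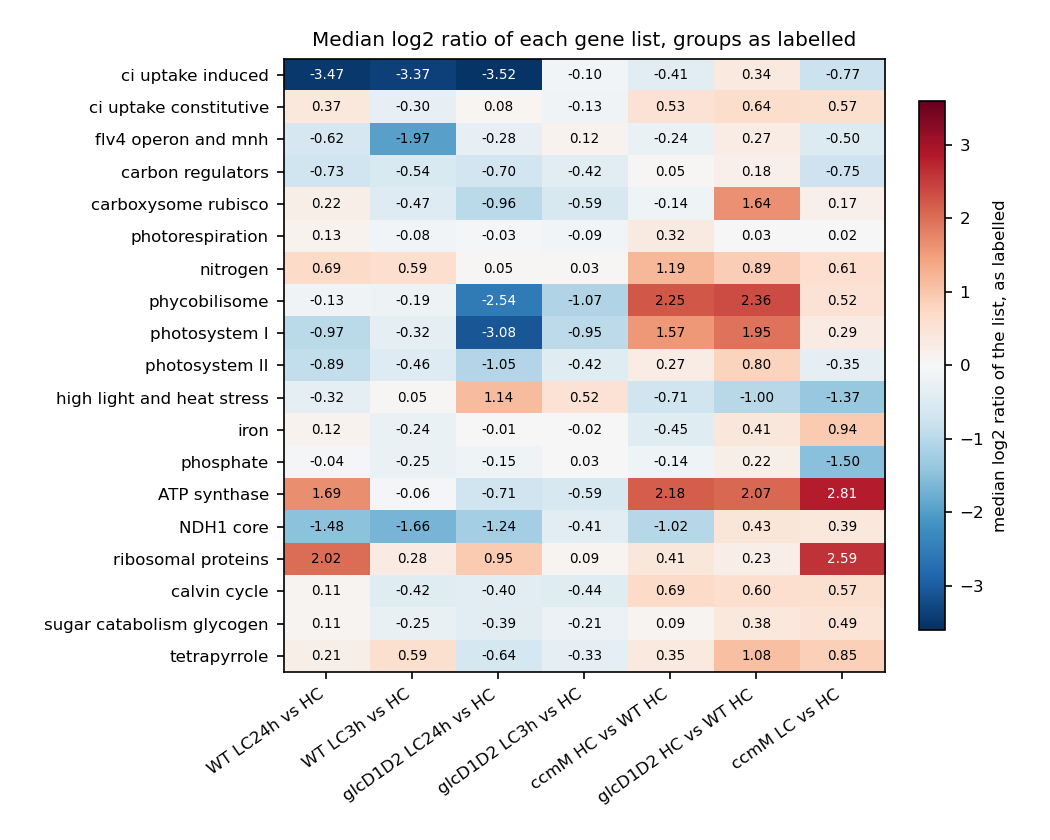
Median log2 ratio, as labelled, of each of the 19 gene lists in each comparison, as a colour map with the value in each cell. The induced uptake list ranged from -3.52 in glcD1D2_LC24h against glcD1D2_HC to 0.34 in glcD1D2_HC against WT_HC among the comparisons against high carbon.

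The last comparison asked whether either mutant at high carbon resembled low-carbon cells. Across 3264 genes, which are not independent replicates, the ccmM_HC effect correlated with the mean LC response at Pearson r = 0.139 (Spearman 0.0955) and the glcD1D2_HC effect at r = -0.267 (-0.271). With the dye-bias correction these were 0.304 and -0.290. Of the markers, flv2, flv4, sll0218, cupA and ndhD3 fell in ccmM_HC as in WT_LC24h, and cmpA passed in neither effect. The 2 mutant effects correlated at r = 0.633 (0.614) and shared 199 genes higher in both (72.1 for independent lists) and 189 lower in both (83.2), with the mutant in Cy3 on both kinds of array, so that a dye bias enters both alike. The WT and glcD1D2 responses correlated at r = 0.386 (0.217) at 24 h, with 84 genes higher in both (26.0) and 125 lower in both (36.7), and at r = 0.0308 (0.194) at 3 h. Within WT, 24 h and 3 h correlated at r = 0.439 (0.235), with 41 genes higher in both (15.2) and 85 lower in both (22.5). The ccmM_LC ratios correlated with WT_LC24h at r = 0.657 (0.667) and with glcD1D2_LC24h at r = -0.0335 (-0.0172). No sample record served 2 comparisons, but the labels do not say whether HC samples of different arrays came from the same cultures, which would raise these correlations and overlaps.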

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

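Tests of the label reading and of the 3 h glcD1D2 arrays were chosen after those results were seen, and the tests of the shared mutant effect before. The level of glcD2 on 1 of 8 samples labelled WT_HC lay apart from the others. It stood at 9.63 on WT_LC24h array 2, and its gap to the nearest sample was 0.597 of the group's range. This was 1 such sample among 26 levels tested, and chance gives about 1 in 20 groups. No explanation for it was tested. Differences between groups under the same contrast were found by tests of the difference itself: limma called 324 genes between the 24 h and 3 h responses, 312 and 193 between the glcD1D2 and WT responses at 24 h and 3 h, and 246 between the ccmM and glcD1D2 effects at high carbon. The count of 838 between the ccmM and glcD1D2 low carbon responses is not read as a difference found, because the spread of the lone ccmM_LC array was never measured. Genes that differed included gifA and psbA3 between the strains at 24 h, hliB and cmpA at 3 h, and flv2 and flv4 between the mutants.

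Uptake genes, led by cmpA and sbtA, fell at low carbon in WT and glcD1D2_LC24h and ccmM rose in its own mutant, both as labelled. A dye bias of the probes is argued against, since the induced uptake list kept a median of -3.39 in the mean 24 h response, where such a bias cancels, and a true response of correctly labelled samples is argued against too, since ccmM differed by 4.42 on the log2 scale between samples labelled ccmM_HC on 2 kinds of array. An exchange of the dye labels on all 13 arrays fits best. Among all ways to keep or exchange them it ranked 1, with the lowest spread within groups (SD 0.378 against 0.538 as labelled, ranked 5832). Then 17 of 17 channels tested correlated best with one of their own group, against 2 of 17 as labelled. With the dyes exchanged, the fit by group called 730 genes for WT_LC24h and 642 for ccmM_HC, where limma called 0 (231 and 240 at an unadjusted p under 0.05) as labelled, with ccmM at -3.29 in ccmM_HC and cmpA at 6.19 in WT_LC3h. This argues against the labels as given: directions of ratios within arrays would turn, and their gene counts stay, with higher and lower traded.

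The 2 glcD1D2_LC3h arrays differed from each other, at r = 0.508 across genes, and uptake genes such as cmpA and sbtA did not pass there. Dim arrays are argued against, since at least 99.954% of their spots were well above background in each channel. The difference between arrays 1 and 2 in Cy5 correlated across genes at 0.909 with the same difference on the glcD1D2_HC against WT_HC arrays of the same slide (0.722 in Cy3), and at 0.742 between the dyes of the 3 h arrays. As labelled, these Cy5 channels are glcD1D2_LC3h and WT_HC, so RNA or cultures behind replicate numbers explain 0.909 only with the dyes exchanged. With 24 h arrays on another slide r was also 0.483. In 26 of 26 labels the replicate number is the array's place on its slide, so place and material cannot be told apart. Genes are not independent replicates, and a true lack of response at 3 h in this strain stays open and untested.

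The 2 mutants shared effects at high carbon, with cpcB and cpcA higher and gifB, nblA1 and hspA lower in both as labelled. A cause in 1 ccmM array stays open. Both arrays correlated with the glcD1D2 effect across genes (r = 0.373 and 0.694), but a shared dye bias gives this too. A dye bias of the probes stays open, because both mutants lay in Cy3: holding the dye term of the low carbon arrays constant, the correlation went from 0.633 to 0.262, and each effect correlated with that term (r = -0.711 and -0.708). The dye term contains strain differences in the responses, so dye bias and a shared mutant effect, which the design names, cannot be told apart here.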

How the results depend on the processing

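The stricter filter, the fits without the glcD1D2_LC3h arrays and of slide 4 alone and the fit with the replicate number as a block were chosen after the data had been seen. Where counts differed by over 1.5 times, the cause was not tested. Of the named genes, cmpA, sbtA and flv2 among them, 160 of 160 kept direction and call without background correction, 157 of 160 with processed signals and 158 of 160 with the authors' value table. Of 126 named genes 15 no longer passed with the dye-bias correction, and of 428 gene values with an array left out 26 no longer passed. Of 137 named genes past the threshold 17 moved by over 1.5 times in fold with an array left out. Many genes whose call or size rested on 1 array were dropped from the text after this check, so these shares describe the genes still named and not all genes. Of 122 list medians past the threshold 50 moved by over 1.5 times in fold in the fit by group without the shared array and 9 turned sign, and with the dye-bias correction these were 32 and 7 of the 74 in which a dye bias does not cancel. Processed signals moved 3, and the authors' value table and no background correction moved 0. No filter and the stricter filter kept all counts within 1.5 times, as did leaving out the glcD1D2_LC3h arrays for the other comparisons. The median of all genes moved by less than 0.1 without background correction, with processed signals, with the authors' value table and with the dye-bias correction, and was not computed for the other settings. Signal over background limits genes outside the 2771 well above background in both channels on all arrays.

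Without background correction limma called 1101 genes for WT_LC24h, 935 for glcD1D2_LC24h, 1258 in the mean 24 h response, 523 between 24 h and 3 h and 763 between the strains at 24 h. With processed signals these were 1459, 1173, 1526, 741 and 1129, and they were 1100, 1079, 1314, 597 and 811 with the authors' value table, which gave 133 for glcD1D2_LC3h and 419 between the mutants at high carbon. The dye-bias correction gave 323 for glcD1D2_LC24h, 24 for glcD1D2_LC3h (25.0% higher, against 42.7%), 72 and 100 between the strains at 24 h and 3 h (66.0% higher at 3 h, against 50.8%), 220 for ccmM_HC and 543 for glcD1D2_HC, and it moved the correlations of the ccmM and glcD1D2 effects with the low carbon response to 0.304 and -0.290. Slide 4 alone gave 254 for glcD1D2_LC3h, 601 in the mean 3 h response and 313 between the strains at 3 h. Against the 3 h glcD1D2 response alone the count for the lone ccmM_LC array was 516. With the estimated correlation 0 gene lists passed by camera (32 at an unadjusted p under 0.05), against 122.

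The fit with no replicate block, by group without the shared array, called by limma 0 genes for WT_LC24h, WT_LC3h, glcD1D2_LC3h, the mean responses at 24 h and 3 h, 24 h against 3 h, the strains at 24 h, ccmM_HC and the ccmM response against the glcD1D2 response (unadjusted p under 0.05: 231, 390, 311, 152, 82, 199, 422, 240 and 89 genes), 1 for glcD1D2_LC24h, 52 between the strains at 3 h (25.0% higher), 149 for glcD1D2_HC and 104 of at least 2-fold for ccmM_LC (77.9% higher, against 48.4%). Of 160 named values 127 no longer passed in it. It turned flv4 to 0.39 in glcD1D2_LC24h, flv2 and cmpA to 0.0542 and 0.25 between 24 h and 3 h, and hspA to 0.26 in glcD1D2_HC. Between the mutants at high carbon it called 320 genes (65.6% higher, against 40.7%), and flv4 and flv2 went to 1.46 and 0.61, and in ccmM_LC flv4, gifB and nblA1 to 1.88, 0.24 and 0.12. With the replicate number as a block in place of the shared array limma called 49 genes between the strains at 3 h (26.5% higher), 147 for glcD1D2_HC, 329 between the mutants (66.3% higher) and 0 for WT_LC24h, WT_LC3h, glcD1D2_LC24h, glcD1D2_LC3h, the mean responses, 24 h against 3 h, the strains at 24 h, ccmM_HC and the ccmM response against the glcD1D2 response (unadjusted p under 0.05: 228, 395, 265, 299, 147, 77, 215, 411, 215 and 79). It was not fitted for ccmM_LC and turned the other genes just named, with flv4 and flv2 at 1.37 and 0.56 between the mutants.

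With 1 array left out, in which case a lone array is assumed to vary like the others, the counts were 101 to 515 for WT_LC24h, 53 to 100 for WT_LC3h, 214 to 507 for glcD1D2_LC24h, 0 to 6 for glcD1D2_LC3h (292 and 475 at an unadjusted p under 0.05), 356 to 780 and 81 to 195 for the mean responses, 97 to 352 for 24 h against 3 h, 12 to 221 and 33 to 81 between the strains, 72 to 1330 for ccmM_HC, 143 to 1042 for glcD1D2_HC, 38 to 360 between the mutants and 481 to 771 for ccmM_LC against the glcD1D2 response. Slide as a random block could not be judged, because each kind of array lay on 1 slide and limma's estimated correlation was 0.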

Other observations

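The tests of other splits were set before the result was seen. Directions below are as labelled. Chlorophyll and bilin synthesis genes of the tetrapyrrole list differed in several comparisons. Of 14 genes 9 rose (9 rose and 1 fell over the list alone) in glcD1D2_HC, with chlN (log2 1.81). The tetrapyrrole median was 1.08 (adjusted p = 0.00146, or 0.552 with estimated correlation), 0.44 in the group fit and 0.48 with the dye-bias correction. In WT_LC3h 6 rose (6 rose and 1 fell over the list alone). For the tetrapyrrole list the median was 0.59 (adjusted p = 0.0120, or 0.624 with estimated correlation), 0.00 with the dye-bias correction. In glcD1D2_LC24h 7 fell (1 rose and 9 fell over the list alone). The tetrapyrrole median was -0.64 (adjusted p = 0.0172, or 0.628 with estimated correlation), and it went to -0.0996 with the dye-bias correction. Without array 1 these counts were 3, 0 and 1. Of 10 iron genes 3 rose and 1 fell (4 rose and 1 fell over the list alone) in WT_LC24h (adjusted p = 0.369). Between the mutants at high carbon 6 fell (7 fell over the list alone), with futC (log2 -1.85). The iron median was -0.92 (adjusted p = 7.35e-06, or 0.121 with estimated correlation). In ccmM_HC the phosphate list had a median of -0.14, a mean of 0.02 and a test pointing down (adjusted p = 0.961). Of 8 Calvin cycle genes 3 rose and 1 fell (the same over the list alone) in glcD1D2_HC (adjusted p = 0.124). Of 16 sugar catabolism and glycogen genes 8 rose and 2 fell (9 rose and 2 fell over the list alone) there, with glgB (log2 -1.11) lower. The sugar median was 0.38 (adjusted p = 0.0434, or 0.596 with estimated correlation). In glcD1D2_LC24h, of these sugar genes 2 rose and 6 fell (2 rose and 7 fell over the list alone). For the sugar list the median was -0.39 (adjusted p = 0.0326, or 0.572 with estimated correlation). On the ccmM_LC array the medians of the phosphate, iron, tetrapyrrole, sugar and Calvin cycle lists were -1.50, 0.94, 0.85, 0.49 and 0.57, at percentiles 0, 99.99, 99.97, 99.5 and 65.4 among random lists.

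Other splits were fitted for comparisons with at least 3 arrays a side or 4 in all. In the mean 24 h response 1 of 8 sign patterns, the real one, called as many genes (822, highest other 312), and in the mean 3 h response also 1 of 8 (365, highest other 193), which are too few patterns for a share under 0.05. With strain as a term, 1 of 34 splits of the 8 low carbon arrays called genes by limma, the real one with 179. It parts 24 h from 3 h (734 at an unadjusted p under 0.05, highest other 556). Most others part replicate arrays, which raises their spread, so chance is not excluded. The real split also parts slide 4 from slides 1 and 3, so slide and time cannot be told apart for genes like cupA and hliB.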
